A study of Arabidopsis thaliana with 12 samples.

How the data were processed

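The 12 arrays came from 6 samples of water-treated plants and 6 of plants given 100 mM proline for 3 h, grouped by the sample labels. The deposited values are relative intensity on a linear scale, never negative, with exact zeros and a ceiling of 100. How the authors subtracted background, scaled the arrays or chose the ceiling is not given in the sources used here. The plant part and the growth conditions are also not given, nor is whether replicates came from separate plants, so p-values measure the spread between these samples, which may be technical. The median log2 intensity of the columns ranged over 0.35, and their interquartile ranges ran from 1.95 to 2.54.

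Intensities were put on the log2 scale with zeros as missing and quantile normalized, because the column medians differed by more than 0.1 and the interquartile ranges by more than 10%. A feature was tested when at least 4 of 6 samples in each group had a value, which left 2861 of 3439 features. Of the 578 others, 201 were at 0 on all 12 arrays. Levels are printed as means ± SD of the deposited intensities with zeros included, while changes and folds come from the normalized log2 values without zeros. Proline was compared with water by limma 3.58.1 (lmFit and eBayes, no block) in R 4.3.3, two-sided, with Benjamini-Hochberg adjusted p under 0.05 over all tested features. Random blocks used statmod 1.5.0. At the ceiling on all 12 arrays were 3 features, and no feature at the ceiling in every sample of a group was among the calls.

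Genes were named through GEO's platform annotation, which is old, only for features with 1 gene, and 690 of these 692 matched a locus of the TAIR10.1 gene table. Of the 576 that were tested, 268 changed, 121 higher and 147 lower. The named genes are the 12 with the largest rise and the 12 with the largest fall among those past the threshold, every gene of proline metabolism and transport, and from each other list the 4 with the smallest p. This rule, the 16 gene lists, the test and the first set of alternatives were chosen before the data were examined. No member was dropped for a name that contradicted its list, and no plastid- or mitochondrion-encoded gene had a feature. A list of at least 5 genes was tested with camera on gene means, with a preset inter-gene correlation of 0.01, and with an estimated correlation and with fry on genes with a value on every array. Measures with a single value per array (zeros, median, interquartile range) were compared by an exact permutation test over the splits of the arrays. This test treats all arrays as separate.

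Both groups carry replicate numbers 1 to 6 in the labels, which do not say what a shared number means. Over 2674 features with all 12 values, the deviations of same-numbered samples from their group means correlated at 0.403, 0.370, 0.255, 0.257, 0.283 and 0.184, and every sample correlated best with its own number in the other group. The numbers therefore pair the samples, from the data and not from the labels, and the fit with the replicate number as a block is given where it changed a call. Within a group, replicates 1 and 2, 3 and 4, and 5 and 6 also deviated together (mean correlation 0.206, against -0.299 between such pairs), so pairs were averaged as an alternative. Subtracting group means makes correlations within a group negative on average, so the value between pairs is no separate result.

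The calls were tested on simulated data made from the 2861 features with 200 of them changed. With independent samples, 91.2% of log2 changes of 2, 73.4% of 1 and 37.3% of 0.5 were found, with 3.99% false calls. With samples correlated within replicate pairs, 27.4% of the calls on 12 samples were false, and 4.63% with the pairs averaged, where 83.6% of log2 changes of 2, 58.8% of 1 and 5.67% of 0.5 were found. The simulated pair effects were drawn separately in each group. In the data, members of a pair also resembled each other across the groups (mean correlation 0.132 for different numbers), so these shares do not carry over to the data. The alternatives were other scalings, filters and treatments of zeros, the replicate number as a fixed or random block, array weights, other tests and thresholds, and leaving out each sample. Added after the data were seen were averaging the pairs, treating them as a random block and leaving out each pair.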

Results

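The series measured RNA from wild-type Arabidopsis thaliana of the ecotype Wassilevskija on 12 one-colour arrays, 6 from plants given water and 6 from plants given 100 mM proline for 3 h. The sample titles give a time for the proline samples only, so from them a difference in time cannot be told apart from proline. Proline is an amino acid that many plants accumulate under drought and salt and that is harmful in excess, and per the labels the dose was meant to bring cellular proline to toxic levels. Each array reported 3439 features as a relative intensity with a ceiling of 100. Between 453 and 534 features per array were listed at 0, 484 ± 21.2 in water and 506 ± 21.7 after proline (SD, n = 6 each, exact permutation test, two-sided p = 0.115). Signal over background was not given in the sources used here, so how far noise limits dim features cannot be stated. The number of arrays limits the precision, as does the resemblance of successive replicates within a group (consensus correlation 0.52 across features). Of the features, 692 carried 1 gene name, 870 carried several and 1877 had none given, so genes are named below from the first kind alone.

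Proline treatment for 3 h was accompanied by changes in a large share of the measured features, with the largest changes upward. Among 2861 features tested, 1263 (44.1%) changed, 523 higher and 740 lower after proline (limma with Benjamini-Hochberg adjustment). Changes of at least 4-fold were found for 54 features that rose and 13 that fell, and the median absolute log2 change of the features that changed was 0.73. A plastid protein with a PsbP domain, a guanylate kinase and a histidine biosynthesis enzyme were among the named genes that rose most, and cyanase was among those that fell most. Within the 3 successive pairs of replicate numbers, 1230 of the 1263 (97.4%) had the same direction in all 3, as did 62.1% of all tested features and 34.2% of those that did not pass. The first share is high in part because these features were picked for passing the test. The groups did not overlap for 736 of the 2674 features with a value on every array. Chance would give a share of 0.216% if all 12 arrays were separate, and a larger one where successive replicates resemble each other. An unadjusted p under 0.05 was found for 1471.

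The balance of higher and lower calls depended on the scaling, and the number of calls depended on whether all 12 arrays count as separate. In the values as deposited the median log2 change of all tested features was 0.057, against -0.12 after quantile normalization, and 702 features were higher and 483 lower. With replicates 1 and 2, 3 and 4, and 5 and 6 of each group averaged, an analysis chosen after the data were seen, 661 features changed, 321 higher and 340 lower, and 656 of them were among the 1263.

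**Figure D1:**
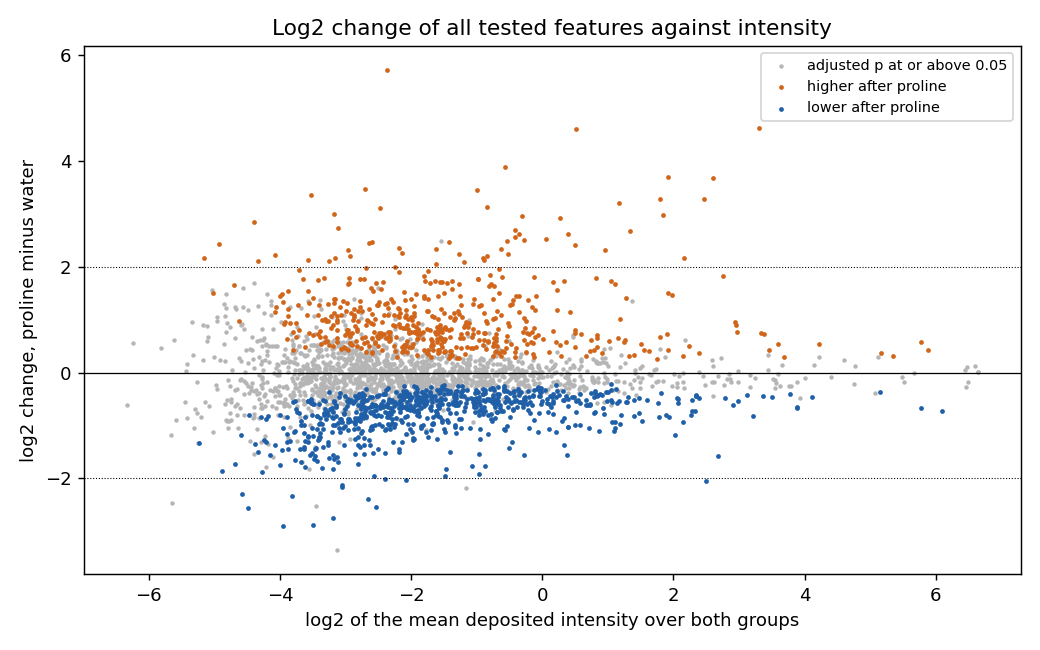
Log2 change (proline minus water) of the 2861 tested features against the log2 of their mean deposited intensity over both groups, each point a feature, coloured by direction where the adjusted p was under 0.05, with dotted lines at changes of 4-fold. Points beyond the upper line (54 that rose) outnumber those beyond the lower one (13 that fell), and most of the latter lie at low intensity.

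The 12 named genes with the largest rise ranged from 2.25 to 5.72 on the log2 scale. AT4G18180, a pectin lyase-like protein, rose 24.3-fold (log2 4.60 ± 0.14 SE, adjusted p = 3.18e-10), from a deposited intensity of 0.110 ± 0.0199 to 2.76 ± 0.212 (SD, n = 6). AT1G76450, a PsbP-domain protein of the chloroplast thylakoid, rose 12.9-fold (log2 3.69 ± 0.15 SE, adjusted p = 2.97e-09), from 0.451 ± 0.122 to 7.08 ± 0.471. AT3G06200, a guanylate kinase, rose 9.76-fold (log2 3.29 ± 0.098 SE, adjusted p = 3.18e-10), from 0.887 ± 0.0878 to 10.2 ± 1.03. AT-HF (AT4G26900), also called HISN4, catalyses a step of histidine biosynthesis and rose 5.92-fold (log2 2.56 ± 0.13 SE, adjusted p = 1.84e-08). AT1G12800, with an S1 RNA-binding domain, rose 6.39-fold, and the carbohydrate kinase-like AT1G06730 rose 9.70-fold. The protein kinase AT5G40030 rose by 2.32 on the log2 scale and the ClpX-like AT5G49840 rose 4.76-fold. AT2G36480 (6.17-fold), AT3G44570 (5.55-fold) and AT5G52530 (10.2-fold) completed the group with AT5G15280, a pentatricopeptide repeat protein. AT5G15280 had the largest log2 change, 5.72 ± 0.38 SE, but was listed at 0 in water replicates 1 and 2 and at 0.0161 or less in the other water samples, against 0.382 ± 0.0881 after proline (SD, n = 6), so its fold rests on 4 water values near the lower end of the scale. Without water replicate 3 the log2 change of AT5G52530 was 2.62 instead of 3.35 (adjusted p = 2.36e-05), and its water replicate 5 was listed at 0. All 12 kept an adjusted p under 0.05 with the replicate pairs averaged, the highest being 0.0149 for AT5G52530. For AT5G15280 the average of water replicates 1 and 2 was missing. Its adjusted p there (0.00254) rests on the remaining water averages, which were near the lower end of the scale.

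The 12 named genes with the largest fall ranged from -2.89 to -1.41 on the log2 scale, and most were dim. CYN (AT3G23490), the cyanase that breaks down cyanate, fell 4.12-fold (log2 -2.04 ± 0.16 SE, adjusted p = 1.30e-06), from 8.83 ± 1.68 to 2.43 ± 0.599 (SD, n = 6). AT1G08845 fell 7.41-fold (log2 -2.89 ± 0.52 SE, adjusted p = 0.00101), from 0.157 ± 0.0507 to 0.0203 ± 0.0213. Its proline replicate 2 was listed at 0, so its fold rests on 5 proline values near the lower end of the scale. AT4G16060 fell 5.90-fold, the protein phosphatase AT4G33500 fell 4.05-fold and AT2G33180 fell 3.86-fold. GH9B12, a glycosyl hydrolase of family 9, fell 2.85-fold, DRT101, named for DNA damage tolerance, fell 2.88-fold, and AT2G35490, a plastid lipid-associated fibrillin, fell 2.66-fold. AT2G43990 fell 2.67-fold. AT1G11800 fell 3.32-fold, with its proline replicate 2 listed at 0. Its adjusted p of 0.00915 became 0.0752 with the replicate pairs averaged, or 0.0549 with the pair as a block besides. It was 0.119 with zeros set to the lowest value and 0.0790 without replicates 5 and 6 of both groups. AT3G57630, an exostosin-family glycosyltransferase, had a log2 change of -1.86 and an adjusted p of 0.0424, or 0.0305 with the pairs averaged. With the pairs as a random block the p was 0.245, with zeros set to the lowest value it was 0.0909, and without replicates 3 and 4 or 5 and 6 of both groups it was 0.124 or 0.169. It rose to between 0.0521 and 0.0835 without any of water replicates 1, 2, 3, 4 and 6 or proline replicates 2, 4, 5 and 6, with log2 changes of -1.97 to -1.42. AT4G39760 had a log2 change of -1.47 and an adjusted p of 0.0401, which was 0.147 with the pairs averaged and 0.0596 with the replicate number as a block. Its proline replicate 3 was listed at 0, and with zeros set to the lowest value its adjusted p was 0.190. Its p was 0.0537 to 0.0899, with log2 changes of -1.54 to -0.95, without any of water replicates 1, 2, 4, 5 and 6 or proline replicates 1 and 2. Without replicates 1 and 2 of both groups its log2 change was -0.36 (adjusted p = 0.340), so its size rests on that pair.

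**Figure D2:**
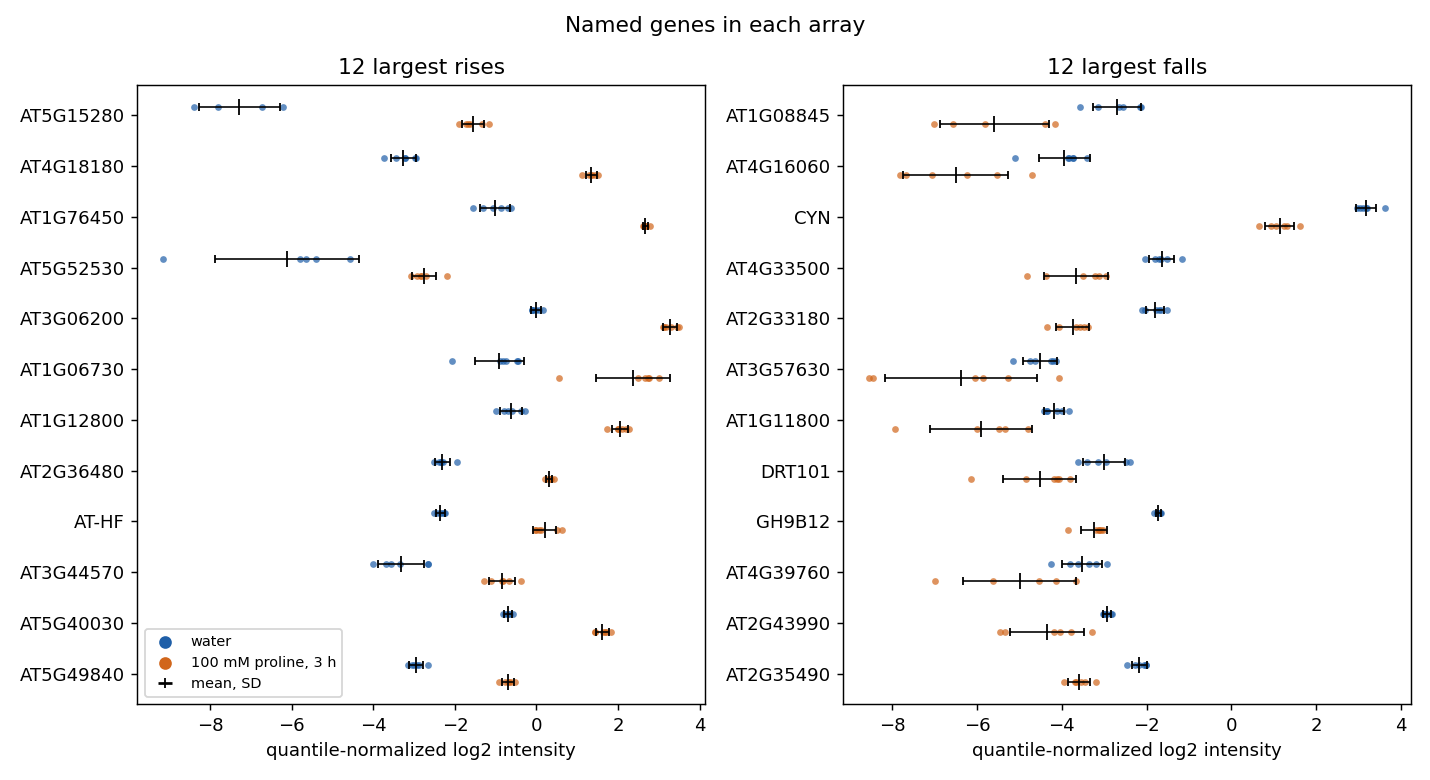
Quantile-normalized log2 intensity of the 12 genes that rose most and the 12 that fell most, with a point per array (6 water, 6 proline), a vertical tick at the group mean and a bar for the SD; values listed at 0 are not drawn. Rises from AT4G18180 to AT5G49840 stand apart from water in every array, while for AT4G16060, AT3G57630 and AT4G39760 the 2 groups overlap.

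Of the 16 gene lists fixed before the data were examined, which covered proline metabolism, nitrogen, osmotic and cold responses, defence, antioxidants, photosynthesis and others, 14 had no tested gene, because few of their 374 genes lay on a feature with 1 gene name. No gene of proline synthesis, breakdown or transport was among those with its own feature. Of the nuclear photosynthesis genes, 5 could be tested, and 1 rose, 3 fell and 1 did not pass. PSBW, a small photosystem II subunit, rose 1.49-fold (log2 0.58 ± 0.11 SE, adjusted p = 0.00120), from 44.3 ± 3.21 to 65.4 ± 7.61 (SD, n = 6). PSAN, a photosystem I subunit on the lumen side, fell by 0.80 on the log2 scale (adjusted p = 0.00249), and PSBY of photosystem II fell by 0.45 (adjusted p = 7.79e-04). PRK, the phosphoribulokinase of the Calvin cycle, had a log2 change of -0.43 (adjusted p = 0.0184), and the light-harvesting gene LHB1B2 had one of -0.26 (adjusted p = 0.223). SBPASE was listed at 0 on all 12 arrays. In the values as deposited PSBY and PRK had log2 changes of -0.18 and -0.19 and adjusted p of 0.169 and 0.322, PRK also missed after cyclic loess (adjusted p = 0.0700), and with the pairs averaged their p were 0.0558 and 0.157. The list's median log2 change was -0.43, with 4 of 5 genes past the threshold when adjusted over the list alone. No shift against the other genes passed the test (camera with a preset correlation, adjusted p = 0.365, and adjusted p = 0.284 with an estimated correlation). Among the dark- and starvation-induced genes, ETFQO, which passes electrons from amino acid breakdown to the respiratory chain, had a log2 change of -1.29 ± 0.70 SE (adjusted p = 0.165).

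A further 8 groups were assembled from the gene names on the array, after those names were read and before their changes were examined. None passed a test against the other genes as a group (camera, adjusted p = 0.997 for each, and adjusted p of 0.700 to 0.741 with an estimated correlation). Single members moved in both directions in 7 of the 8. Of 12 thylakoid complex and assembly genes, 2 rose and 4 fell, against 2 higher and 2 lower as deposited and with the pairs averaged. Among them LPA19, a photosystem II assembly factor, fell by 1.07 on the log2 scale (adjusted p = 1.04e-04). Of 19 pentatricopeptide repeat, mTERF and related organelle nucleic acid genes, 4 rose and 6 fell, and their median log2 change of -0.26 and mean of 0.21 differed in sign. The balance turned with the processing, with 4 higher and 3 lower as deposited and after cyclic loess. With the pairs averaged 3 were higher and 2 lower, or 3 and 1 with the pair as a block besides. Other settings kept more falls, with 4 higher and 9 lower with the replicate number as a block. After median scaling 4 were higher and 5 lower. OSB1, which acts on mitochondrial DNA, rose 2.08-fold (adjusted p = 1.21e-04) and AT2G46050 rose 2.07-fold (adjusted p = 6.93e-04), while AT4G21170 had a log2 change of -0.50 (adjusted p = 4.36e-04) that was -0.13 (adjusted p = 0.169) as deposited. With the pairs averaged its adjusted p was 0.0431, and 0.0654 with the pair as a block. Of 7 plastid ribosome, chaperone and translocation genes, 1 rose and 2 fell. The ribosomal protein gene AT5G65220 rose 2.75-fold (adjusted p = 4.41e-06), and AT3G54210 and SECE1 had log2 changes of -0.65 (adjusted p = 1.30e-04) and -0.90 (adjusted p = 4.45e-04). In this group Cpn60beta4 did not pass (log2 -0.31, adjusted p = 0.158), but passed after median scaling (log2 -0.45, adjusted p = 0.0394) and without replicates 3 and 4 of both groups (log2 -0.58, adjusted p = 0.0426).

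Of 5 tetrapyrrole and carotenoid genes, 4 had a lower normalized value and none a higher one past the threshold, against 3 lower and 1 higher as deposited. CHLM of chlorophyll synthesis, SIRB of sirohaem synthesis and Z-ISO of carotenoid synthesis had log2 changes of -0.65, -0.51 and -1.13 (adjusted p = 0.00467, 0.00541 and 0.0342), and none of these passed with the replicate pairs averaged (adjusted p = 0.0624, 0.0681 and 0.121). With these averages and the pair as a block, CHLM and Z-ISO passed (adjusted p = 0.0357 and 0.0127) and SIRB did not (adjusted p = 0.0967). HEMA3, a glutamyl-tRNA reductase gene, had a log2 change of -0.30 (adjusted p = 0.0459) that was 0.062 (adjusted p = 0.717) as deposited, and an adjusted p of 0.237 with the pairs averaged and 0.178 with the pair as a block besides. Z-ISO was listed at 0 in proline replicate 1, and with zeros set to the lowest value its adjusted p was 0.217. Z-ISO also lost its call, at adjusted p of 0.0503 to 0.0830 and log2 changes of -1.17 to -0.90, without any of water replicates 3, 4, 5 and 6 or proline replicates 2, 3, 4 and 5. HEMA3 lost its own, at 0.0668 to 0.0927 and -0.31 to -0.24, without any of water replicates 3, 4, 5 and 6 or proline replicates 1, 2, 3 and 4. Of 10 amino acid, nucleotide and cofactor genes, 3 rose and 1 fell. With AT-HF, the phosphoribosyl pyrophosphate synthetase AT2G35390 rose 1.76-fold (adjusted p = 0.00145), and the argininosuccinate lyase AT5G10920 had a log2 change of 0.59 (adjusted p = 0.0258), which passed neither without water replicate 5 (log2 0.52, adjusted p = 0.0552) nor without proline replicate 5 (log2 0.50, adjusted p = 0.0562), nor with the pairs averaged (adjusted p = 0.148, or 0.141 with the pair as a block besides). AT1G31220 of purine synthesis fell by 0.52 on the log2 scale (adjusted p = 0.00797, 0.0681 with the pairs averaged and 0.0959 as deposited).

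Of 6 redox genes, 1 rose and 2 fell. NTRC, the plastid thioredoxin reductase, rose 1.57-fold (adjusted p = 0.0146), the plastid lipocalin CHL fell 2.25-fold (adjusted p = 1.68e-04) and GLDH, the last enzyme of ascorbate synthesis, fell 1.42-fold (adjusted p = 0.0181). With the pairs averaged CHL passed (adjusted p = 0.0186), and NTRC and GLDH did not (adjusted p = 0.110 and 0.0932). NTRC also missed after median scaling (adjusted p = 0.0507) and GLDH after cyclic loess (adjusted p = 0.0559). The copper chaperone CCS had a log2 change of 0.73 ± 0.38 SE (adjusted p = 0.140), and of 1.09 (adjusted p = 7.23e-04) without proline replicate 3. Of 5 genes named for stress, 2 rose and 2 fell, against 3 higher and 1 lower as deposited and after cyclic loess. DI21, named for induction by drought, rose 2.99-fold (log2 1.58 ± 0.20 SE, adjusted p = 5.59e-05), and SIS, named for induction by salt, rose 1.93-fold (adjusted p = 0.00592, 0.0593 with the pairs averaged and 0.0387 with the pair as a block besides). XERICO, a RING protein of abscisic acid responses, had a log2 change of -0.39 (adjusted p = 0.0144, 0.157 with the pairs averaged, 0.242 as deposited and 0.135 after cyclic loess). Of 5 carbon metabolism genes, 2 were higher and none lower as deposited, while after quantile normalization PRK fell and the sucrose phosphate synthase gene ATSPS4F rose 1.32-fold (adjusted p = 0.0225, 0.168 with the pairs averaged). PPDK had a log2 change of 0.29 (adjusted p = 0.0834), with a p of 0.0205 with the replicate number as a block, 0.164 with the pairs averaged, 0.182 with the pair as a block besides, 0.0490 without proline replicate 1 (log2 0.35), 0.00306 as deposited and 0.0196 after median scaling. In this group AT4G17260, a lactate dehydrogenase gene, had one of -0.62 (adjusted p = 0.425).

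**Figure D3:**
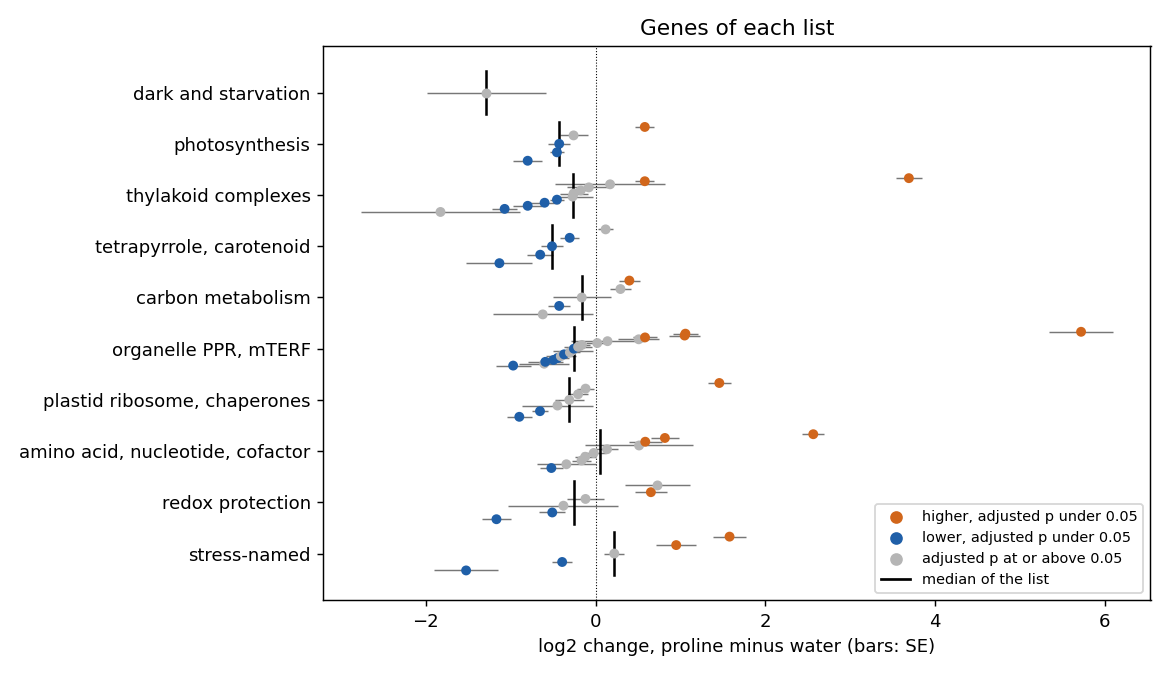
Log2 change (proline minus water) of each tested gene, grouped by list, with bars for the SE and a black line at each list's median; colours mark direction where the adjusted p was under 0.05. Most lists hold changes in both directions, and the medians run from -1.29 (1 gene) to 0.22.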

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

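The tests of the replicate numbers, of the replicate pairs and of the large rises and falls were chosen after the result was seen. Cyclic loess was among the scalings chosen at the outset, but was used as a test of an explanation only after its count was seen. The other tests in this part were chosen before. Of 114 groups of 4 to 6 values, 9 held a sample farther from the rest than Dixon's limit for a group of that size, where chance gives about 5.7. In water replicate 3, AT5G52530 had a normalized log2 intensity of -9.15, with the other 4 values between -5.79 and -4.56 and replicate 5 listed at 0. AT1G06730 was low in replicate 3 of both groups, at -2.08 in water (others -0.89 to -0.46) and at 0.56 after proline (others 2.49 to 3.00). AT4G16060 was at -5.12 in water replicate 2 (others -3.86 to -3.40). CYN was at 3.62 in water replicate 3 (others 2.96 to 3.19). GH9B12 was at -3.85 in proline replicate 4 (others -3.19 to -3.03). AT4G21170 was at -0.17 in water replicate 3 (others -0.35 to -0.29). AT5G65220 was at 1.30 in water replicate 1 (others 0.92 to 1.06). CCS was at -5.55 in proline replicate 3 (others -3.47 to -3.02), and without that sample its log2 change was 1.09 (limma, adjusted p = 7.23e-04).

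Every proline array had a wider spread of log2 intensities than every water array, with an interquartile range of 2.47 ± 0.049 against 2.03 ± 0.048 (SD, n = 6, exact permutation test, two-sided p = 0.00216, the smallest the splits can give, adjusted p = 0.00433 over 4 measures). The test treats the arrays as separate, though successive replicates of a group resemble each other, so its p may be too small. Among the brighter features the difference in interquartile range was 0.011 (1.71 ± 0.033 against 1.70 ± 0.029), and among the dimmer ones it was 0.31. A background subtraction that differed between the groups may therefore account for the widening, and a response of dim transcripts to proline stays open, untested. An intensity-dependent scale difference as the whole source of the calls is argued against by cyclic loess normalization, after which 1203 features changed, 1126 of them among the 1263 and all of these 1126 with the same sign. Calls were more frequent in the brightest 715 features (50.6%) than in the dimmest 716 (30.6%). The median log2 intensity, with zeros left out, was also higher in every proline array than in every water array. It was -2.02 ± 0.0575 against -2.22 ± 0.0604 (SD, n = 6, exact permutation test, two-sided p = 0.00216, adjusted p = 0.00433, arrays taken as separate). Quantile normalization removed this shift, and its cause was not tested.

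Samples with the same number deviated together across the groups, with a mean correlation of 0.292 across features (exact permutation test over 720 matchings, one-sided p = 0.00139, the smallest they can give). A measurement effect tied to each number and shared by both groups may be the source. Within groups, replicates 1 and 2, 3 and 4, and 5 and 6 gave the highest mean correlation of the 15 possible pairings in both groups, with a consensus correlation of 0.52. Across the groups, different numbers of the same pair correlated at a mean of 0.132, against -0.105 for other pairs. Water and proline samples cannot share 1 extract, so 1 extract per pair is not the whole source of the resemblance. Whether the 2 members of a pair within a group are repeat measurements of 1 extract or separate plants handled together cannot be told apart. The labels name no extract. No biological explanation was tested, since the labels give the numbers no meaning.

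Rises of at least 4-fold (54) outnumbered falls of that size (13). Among the 851 features with a water mean of at least 0.395, which can fall 4-fold and stay at or above 0.0986, the 25th percentile of the lower group's mean, 9 rose and 1 fell by that much (exact sign test, two-sided p = 0.0215, over features that are not independent), which argues against values close to 0 as the reason there. Among the dimmer features 45 rose and 12 fell, and a response cannot be told apart from the low end of the scale, which limits the falls. In the values as deposited there were 59 rises and 16 falls, which argues against the quantile normalization. For the dimmer features a difference in background also stays a possible source.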

How the results depend on the processing

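The number of changed features stayed within 1.5 times of 1263 under every scaling, filter, weighting and test tried, from 880 at an adjusted p under 0.01 to 1423 with a random replicate block, except for 3 settings. It was 661 with the replicate pairs averaged, 692 with these averages and the pair as a replicate block, and 374 when a change of at least 2-fold was also asked for. Averaging leaves fewer values per group, and where samples correlate within pairs it also removes false calls. In simulated data with 200 of 2861 features changed, false calls made up 27.4% of calls on 12 samples and 4.63% after averaging. Fewer features were changed there than were called here, so that share does not carry over to the 1263 calls. Correlation across groups, of same-numbered samples or of replicate pairs, was not simulated. How much of the drop the fewer values and the removed false calls each account for was not tested. With the replicate number as a block it was 1360, and 1196 of the 1263 calls were kept. Leaving out 1 sample gave 1188 to 1218. As deposited 922 of the 1263 calls were kept and 27 of the calls had the opposite sign. Averaging the pairs, the pair block, the random pair block (887) and leaving out pairs (973 to 1074) were chosen after the data were seen.

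The photosynthesis list did not pass camera under any alternative, with medians of -0.45 to -0.36 when 1 sample was left out, -0.18 as deposited and -0.24 without replicates 5 and 6. The limma function fry passed at the same median of -0.43, with a directional adjusted p = 9.58e-04 and a mixed adjusted p = 9.59e-04, but it does not compare a list with other genes. It passed 5 of the 8 added lists in the directional form and 6 in the mixed form. Of the 49 named genes that changed, 34 kept the call with the pairs averaged and 15 lost it, 13 lost it with the pair as a block besides and 9 with the random pair block, and 5 lost it when some 1 sample was left out. Calls were also lost for 6 named genes as deposited, HEMA3 with its sign reversed, 5 after cyclic loess, 4 with zeros filled and 2 after median scaling. Leaving out replicates 1 and 2, 3 and 4, or 5 and 6 of both groups lost 7, 10 and 8. With the replicate number as a block, AT4G39760 lost its call and PPDK gained one, and no other named gene or list changed its call.

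HEMA3 reversed as deposited (0.062, not called). Among the added lists, none of which passed, the median changed sign for carbon metabolism without replicates 3 and 4 (0.18) and for the pentatricopeptide repeat list as deposited (0.035). It did so for the amino acid list without the dimmest features (-0.022), with only complete features (-0.022), with zeros filled (-0.0077), and without replicates 1 and 2 (-0.012) or 5 and 6 (-0.011), and for the redox list with pairs averaged, with or without the block (0.013), and without replicates 5 and 6 (0.37). The cause was not tested. Without a background measure, changes of dim features stay the least certain.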

Other observations

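A few features were above 0 on every array of one group and listed at 0 on every array of the other. There were 5 such features in water and 3 after proline. Among the former was SRX (AT1G31170), the sulfiredoxin that repairs overoxidised peroxiredoxins, with an intensity of 0.0539 ± 0.0228 in water (SD, n = 6). SRX was chosen for mention after its values were seen. Its water values ran from 0.0247 to 0.0826, below 0.0986, the 25th percentile of the lower group's mean over the tested features. At this level a response cannot be told apart from a difference in background between the groups. The brightest of the 3 features above 0 only after proline had no gene given. It had an intensity of 1.37 ± 0.251 after proline, from 1.03 to 1.65. AT4G31530 was at the ceiling on all 12 arrays, so no comparison could be made for it.

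Several of the largest changes belong to features with no gene given. Feature 733 rose 24.7-fold, from 0.680 ± 0.118 to 19.0 ± 2.74 (SD, n = 6, limma adjusted p = 4.57e-10), and feature 248 rose 14.7-fold (adjusted p = 0.00270). Feature 937 fell 7.42-fold (adjusted p = 0.00440) and feature 1444 fell 6.72-fold (adjusted p = 0.0158). All 4 passed with the replicate pairs averaged, at adjusted p of 2.55e-04, 0.0327, 0.0127 and 0.0404.

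Of 100 splits of the 12 samples into equal groups, 1 gave as many changed features as the real one, namely the real split itself with 1263. The highest other gave 1. Every other split mixes water and proline arrays, which widens the spread within its groups and lowers its count. The comparison also treats all 12 samples as exchangeable, while successive replicates resemble each other, so it does not exclude chance. The real split parts all 6 replicate numbers. Another 11 of the drawn splits did the same, and each of these gave 0. With the replicate pairs averaged there are only 10 splits, too few for a share under 0.05, and the real one, 1 of the 10, gave 661 features against a highest other of 0.

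The log2 changes computed within the pairs of replicates 1 and 2, 3 and 4, and 5 and 6 correlated at 0.644, 0.610 and 0.659 across features, which are not independent replicates.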
